A study of Mus musculus with 8 samples.

How the data were processed

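Messenger RNA profiles of embryonic mouse stomach were analysed at E13.5, with 4 wild type libraries and 4 YAP5SA libraries, the groups and replicate numbers being taken from the labels. Per the labels' protocols, stomachs were frozen, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.2.1 and Cuffdiff were used with the mouse build mm10, without a role or an order for each. Read filters, the treatment of duplicate fragments and the use of strand were not given in the sources used here.

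Per the file headers, the deposited table of 26747 assembled loci gives raw fragments for each library, which are estimated counts: 10.9% to 11.3% of the values per library were not whole. The same deposited table gives FPKM, scaled between libraries by the authors, and another deposited table gives group FPKM values, which equalled the mean of the 4 libraries within 0.01. A table of group counts was not used because it holds no single libraries. Fragment counts were rounded to whole numbers. Loci without a gene name, 3582 in all with 1.85% to 1.97% of the fragments, stayed out of library sizes and tests and were tested apart. Joined loci that carry several gene names (591) and further loci of an already listed name (582) were kept as separate loci. A failed status was attached to 3 of 213976 values, which were kept as deposited. No pair of libraries of a group agreed within counting error, so each library was counted as 1 replicate. The labels do not say whether libraries came from separate embryos or pools, so p-values measure the spread between these libraries.

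Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM library-size factors and the default filterByExpr settings (10 fragments in enough libraries and 15 in total), which left 14574 loci. Genotype was the only term. Calls were two-sided at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are YAP5SA minus wild type. Every adjusted p of a gene below comes from this edgeR test unless another tool is named. Levels are fragment counts scaled to library size (CPM) as mean ± SD of 4 libraries, and fold changes carry a standard error (SE). Data were simulated for 14574 loci, 200 of them changed, with the real means and library sizes and the trend of dispersion with abundance. There the edgeR step recovered 87% of genes changed 2-fold and 69% of genes changed 1.5-fold, and 3.7% of its calls were false. DESeq2 made 10.3% false calls there. The simulation left out dispersion particular to a gene, links between genes and embryo sex, so these shares need not hold for the real data. For genes with 1 to 3 fragments in a group, a ratio of CPM with a 95% counting interval is given. Such intervals cover counting error only.

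A set of 29 gene lists was fixed before the data were examined. Lists on the signalling and mesenchyme of the stomach were smooth muscle, YAP/TAZ/TEAD targets, Hippo pathway components, Hedgehog targets, Hedgehog ligands, receptors and effectors, proliferation, stomach mesenchyme patterning, extracellular matrix, interstitial cell and subepithelial fibroblast markers, BMP and TGF-beta signalling, Wnt targets and modulators, SRF/MRTF and actin cytoskeleton targets, and chondrogenic markers. Lists of other cells were gastric and foregut epithelium, enteric neurons, enteric glia and neural crest, endothelium, erythroid cells, macrophages and leukocytes, mesothelium, spleen primordium, pancreas, liver, skeletal muscle and intestinal epithelium. Lists on tissue state were the immediate-early and heat-shock response, hypoxia and glycolysis, the p53 response and sex-linked genes. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were alternatives. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

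Genes were named by a rule set before the data were examined. It took Yap1, Wwtr1, Nkx3-2, Gt(ROSA)26Sor and Myocd in any case. It took the 12 largest rises and 12 largest falls among called genes with at least 2 CPM on average and no overlap between the genotypes, and up to 4 members of each list with the smallest p. It also took members that a count needs and the most abundant markers of other cell types. The members named beyond the 4 with the smallest p were chosen after their values were seen, as were the Wnt, Hox and collagen genes of the closing observations. Results of some single genes are not reported here. Coordinates are those of the deposited tables on mm10, and gene classes and exon lengths came from GENCODE M21 on the same build, which gave a length for 88.8% of the loci with a single gene name.

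Alternatives set before the data were examined were RLE and upper-quartile library-size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter of 5 CPM in 4 libraries, the replicate number as a block, leaving out each library in turn, leaving out haemoglobin genes, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter. Chosen after seeing the data were embryo sex as a covariate, from Ddx3y fragments, leaving out both libraries numbered 1, and restriction to loci under 0.2 fragments per exonic base. Both genotypes carry replicate numbers 1 to 4 in the labels, which do not say what a number marks. Matching these numbers to the deposited libraries by order is an assumption. Deviations from the genotype means over all tested loci correlated across genes within same-numbered pairs by 0.22, 0.14, 0.14 and 0.21, all above the limit of 0.1, so the numbers were treated as pairing the libraries and the blocked value stands beside each result it changes. Among loci above 32 CPM these correlations were −0.03, 0.41, 0.14 and 0.47. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15.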

Results

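Whole stomachs of wild type mouse embryos were compared with stomachs of embryos carrying Nkx3.2Cre and R26-YAP5SA at E13.5 of gestation. In the second genotype, called YAP5SA here, Cre recombinase expressed from the Nkx3-2 locus, which is active in stomach mesenchyme, switches on a mutant of the transcriptional coactivator YAP that the Hippo kinases cannot inhibit. The comparison asks how gene expression in the developing stomach differs between these genotypes. No library carried Cre without YAP5SA, so effects of Cre at the Nkx3-2 locus cannot be told apart from those of active YAP. The wild type libraries numbered 1 to 4 held 6328344, 6919353, 6892438 and 6491271 fragments, and the YAP5SA libraries 8513116, 7293556, 7631084 and 7682245. The means were 6.66 ± 0.29 M and 7.78 ± 0.52 M fragments (SD, n = 4). Expression profiles correlated at 0.97 to 0.986 within wild type, 0.973 to 0.986 within YAP5SA and 0.936 to 0.955 between genotypes, and the leading principal component, with 51.7% of the variance, separated the genotypes.

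In YAP5SA stomachs, 15 of 23 targets of YAP and its TEAD partners rose, led by Ankrd1, together with genes of BMP and Wnt signalling such as Msx1 and Wif1. Of 24 smooth muscle genes 12 fell (list median −0.40), among them Myh11 from 457 ± 17.0 to 163 ± 49.7 CPM (SD, n = 4). Markers of the gastric epithelium, enteric neurons and enteric glia fell by about 1 on the log2 scale, with list medians of −1.07, −1.05 and −1.04, while macrophage markers rose with a median of 0.67. Genes of the cell cycle had a median of 0.01, but they lie at densely covered loci, where changes may be compressed. Smooth muscle genes, at a median of 0.231 fragments per exonic base, were covered more densely than the epithelial, neuronal and glial lists (0.149, 0.088 and 0.067). The sizes of change of these lists are therefore not compared with each other. At an adjusted p under 0.05, 2757 of 14574 loci differed, of which 1321 were higher and 1436 lower in YAP5SA. The change was at least 2-fold for 919 loci, 373 higher and 546 lower. The genotypes did not overlap in 23.3% of all tested loci, against 2.9% by chance, and in 91.5% of the called loci. Of the 29 gene lists, 14 passed the camera test with a preset correlation. With an estimated correlation camera passed 0 lists, 6 at an unadjusted p under 0.05, while fry passed 15. Since the list tests hung on the correlation used, the results below are given as gene counts. Such counts share that limit, because members of a list can vary together. Estimated correlations ran from −0.01 for the interstitial list to 0.93 for the intestinal list. The counts of a list are to be read beside those over all tested loci, where 1321 of 14574 rose and 1436 fell. Other divisions of the same 8 libraries gave up to 16 lists with the preset correlation. Those with 14 or more kept 3 of the 4 libraries of a genotype together, so they carry part of the genotype difference.

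**Figure D1:**
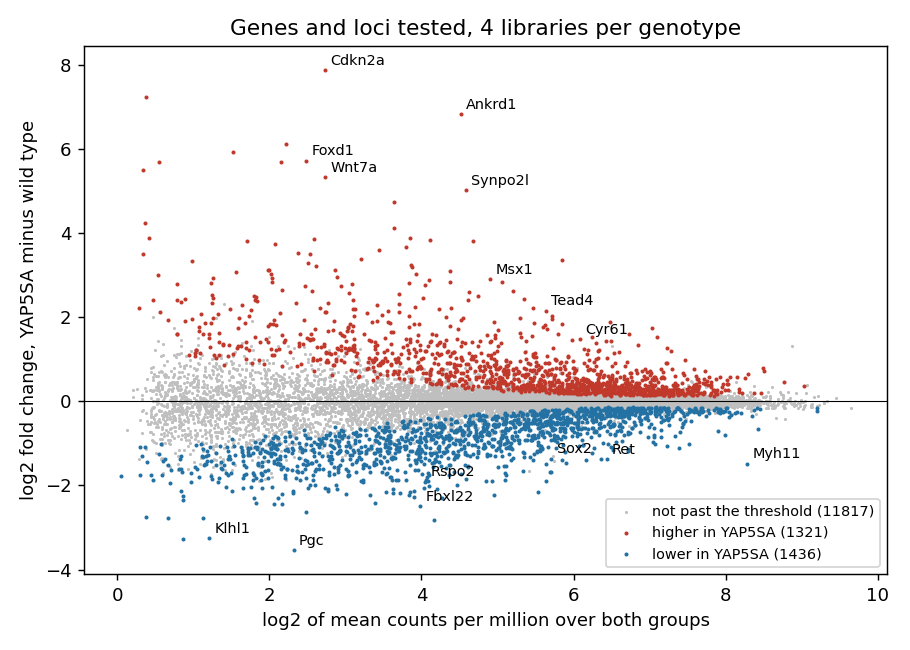
Each point is 1 of the 14574 tested loci, with the log2 of mean CPM over both genotypes on the x axis and the log2 fold change, YAP5SA minus wild type, on the y axis (n = 4 per genotype). Red marks 1321 loci past the adjusted p threshold as higher in YAP5SA, blue marks 1436 as lower, and the fitted position of Cdkn2a, with 1 wild type fragment, depends on the prior count.

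The Yap1 gene itself (locus XLOC_024668, chromosome 9, 7931994 to 8004727, mm10; protein-coding) was at 232 ± 7.46 CPM in wild type and 224 ± 14 CPM in YAP5SA, a log2 fold change of −0.05 ± 0.05 (SE, n = 4, adjusted p = 0.55). How fragments of the transgene were assigned is not given in the sources used here, so this value does not measure it. Wwtr1, which encodes the related coactivator TAZ, stood at 147 ± 12 and 159 ± 10.2 CPM (adjusted p = 0.29), and Nkx3-2, the gene that drives Cre, at 63.0 ± 10.5 and 79.1 ± 14.5 CPM (adjusted p = 0.15). Gt(ROSA)26Sor, the noncoding locus that houses the transgene (chromosome 6, 113046326 to 113153424, mm10; annotated as antisense), was higher by 0.70 ± 0.19 at 26.8 ± 2.33 against 16.5 ± 4.71 CPM (adjusted p = 0.03). That call was lost without wild type replicate 1 (adjusted p = 0.051) or YAP5SA replicate 1 (0.056), 2 (0.065) or 4 (0.057) and in all 3 FPKM fits (0.19, 0.2 and 0.21), and since strand use is not given, fragments of overlapping genes may be included.

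Among the largest rises were a muscle stress-response gene, inhibitors of the cell cycle and developmental transcription factors. Ankrd1 (chromosome 19, 36111964 to 36119844, mm10) went from 0.391 ± 0.398 to 45.4 ± 21.4 CPM (log2 fold change 6.83 ± 0.58, adjusted p = 7.1e-05; 7.69 without wild type replicate 4). Cdkn2a, which encodes the inhibitors p16 and p19, had 1 fragment over the 4 wild type libraries and 410 over the 4 YAP5SA libraries, a CPM ratio of 351 (95% counting interval 62.7 to 13900; chromosome 4, 89274472 to 89294619, mm10). The YAP5SA libraries differed in Cdkn2a, at 24.6, 18.9, 7.29 and 1.88 CPM. The wild type fragment lay in replicate 3, and without that library the ratio was at least 87.2 against a floor of 3 fragments. Its neighbour Cdkn2b rose by 3.89 ± 0.64, and by 4.66 without wild type replicate 1, which was at 4.13 CPM beside 1.32, 0.75 and 1.11. The homeobox gene Alx1 had 3 against 277 fragments (ratio 79.1, interval 26.8 to 386; 46.1, interval 15.4 to 226, without YAP5SA replicate 3, which was at 20.9 CPM beside 5.87, 5.53 and 4.43) and the myelin protein gene Pmp2 had 2 against 174 (ratio 74.6, interval 20.3 to 621). Foxd1, a forkhead transcription factor (5.72 ± 0.51; 6.55 without wild type replicate 1), the relaxin receptor gene Rxfp1 (5.69 ± 0.76), Wnt7a (5.33 ± 0.68; 5.91 without wild type replicate 1), the sarcomere gene Synpo2l (5.02 ± 0.29), the calcium channel gene Cacna1s (4.75 ± 0.38), the basement membrane collagen gene Col4a3 (4.12 ± 0.40) and Ptgs2, which encodes cyclooxygenase-2 (3.86 ± 0.51), also rose. All 4 wild type fragments of Rxfp1 lay in replicate 3, and without that library its CPM ratio was at least 57.8 against the same floor. The largest falls were Pgc, a pepsinogen gene (−3.54 ± 0.58), Klhl1 (−3.26 ± 0.59), the phospholipase genes Pla2g1b (−2.77 ± 0.47) and Pla2g10 (−2.29 ± 0.44), the cytochrome P450 genes Cyp2d26 (−2.62 ± 0.46) and Cyp3a13 (−2.43 ± 0.32), Fbxl22 (−2.50 ± 0.26), Cldn15 (−2.41 ± 0.28), Slc25a21 (−2.41 ± 0.42), Oit1 (−2.29 ± 0.40), Tmprss4 (−2.27 ± 0.31) and Sh3bgr (−2.23 ± 0.24). Without YAP5SA replicate 1, Pgc was at −4.29, Klhl1 at −4.10 and Pla2g1b at −3.52. All 24 kept their call in every alternative that tested them.

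Of the 23 YAP/TAZ/TEAD targets, 15 rose and 1 fell, against 19 and 1 adjusted over the list alone (camera adjusted p = 3.7e-10; adjusted p = 0.077 with an estimated correlation). Besides Ankrd1, the matricellular genes Cyr61 and Ctgf rose by 1.48 ± 0.12 and 0.75 ± 0.18, Cyr61 from 35.8 ± 4.88 to 99.3 ± 13.7 CPM. Nt5e rose by 3.10 ± 0.31, Igfbp3 by 0.68 ± 0.06 and Lats2, a Hippo kinase gene under feedback by YAP, by 0.70 ± 0.05 (adjusted p = 4.3e-05). Foxf2 fell by 0.85 ± 0.15. It is shared with the patterning list, and Tgfb2 with the BMP list. Of 20 tested Hippo pathway components, 5 rose and 0 fell, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.0097; adjusted p = 0.22 with an estimated correlation). Tead4, a DNA-binding partner of YAP, went from 18.1 ± 6.93 to 81.4 ± 10.2 CPM (2.16 ± 0.21, adjusted p = 0.00015), and Vgll3, another TEAD cofactor, rose by 2.04 ± 0.23. Wwc2, Wwc1 and Tead1 rose by 0.54 ± 0.07, 0.43 ± 0.10 and 0.41 ± 0.10, the last without a call under the replicate block (adjusted p = 0.062). The kinase gene Lats1 was not tested within the list. Its own locus was listed at 0 in all 8 libraries, but the joined locus Lats1,Nup43 on the same coordinates (chromosome 10, 7667503 to 7716461, mm10) was at 179 ± 6.38 and 190 ± 12.7 CPM (adjusted p = 0.33), so the 0 does not show an absence of Lats1 transcripts.

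Of the 24 smooth muscle genes, 12 fell and 0 rose, against 15 and 1 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.15 with an estimated correlation). No member is on another list. The smooth muscle myosin gene Myh11 fell by 1.48 ± 0.19 (adjusted p = 0.00051), the calponin gene Cnn1 by 1.22 ± 0.16, the gamma actin gene Actg2 by 1.15 ± 0.10 and Synpo2 by 1.13 ± 0.10. Pdlim3, the myosin light chain kinase gene Mylk and the alpha actin gene Acta2 fell by 0.87 ± 0.08, 0.79 ± 0.05 and 0.45 ± 0.06. Mylk went from 322 ± 10.7 to 186 ± 11.3 CPM (adjusted p = 1.9e-05). Myocd, which encodes the smooth muscle coactivator myocardin, stood at 128 ± 15.9 and 84.4 ± 29.5 CPM (−0.59 ± 0.19, adjusted p = 0.059). YAP5SA replicate 1 was at 128 CPM of Myocd and the others at 64.0, 78.5 and 67.3 CPM, and without that library the adjusted p was 0.00068. DESeq2 and limma-voom also put Myocd past the threshold, at 0.019 and 0.039.

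Hedgehog signalling runs from the epithelium, which makes the ligands, to the mesenchyme, and members on both sides fell while epithelial markers were also lower. Shh fell by 1.18 ± 0.20, from 64.0 ± 10.7 to 28.1 ± 8.49 CPM, and Ihh by 1.49 ± 0.23, from 73.4 ± 10.2 to 26 ± 10 CPM. Of 9 Hedgehog targets, 6 fell and 1 rose, and as many adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.35 with an estimated correlation). The falls included Foxf1a (−0.74 ± 0.08), the receptor gene Ptch1 (−0.71 ± 0.11), Foxl1 (−1.12 ± 0.20), Hhip (−0.88 ± 0.22) and Gli1 (−0.77 ± 0.21), and Bmp4 rose by 0.50 ± 0.09. The list lost its call without YAP5SA replicate 1 (adjusted p = 0.079), and without both libraries numbered 1 (0.11). Only 3 targets fell without YAP5SA replicate 2 or 3. Hhip lost its call without YAP5SA replicate 2 (0.054) or 3 (0.063), and Gli1 without wild type replicate 1 (0.061) or 4 (0.065) or YAP5SA replicate 1 (0.065), 2 (0.067) or 3 (0.085). Gli1 and Foxl1 are shared with the interstitial list and Bmp4 with the BMP list. Among 12 Hedgehog ligands, receptors and effectors, the coreceptor genes Boc and Gas1 rose by 0.57 ± 0.10 and 0.25 ± 0.07 and Disp1 by 0.52 ± 0.10, so 3 rose and 2 fell, and as many adjusted over the list alone. Gas1 lost its call without wild type replicate 2 (0.064) or 4 (0.079) or YAP5SA replicate 2 (0.058) or 3 (0.076). This list had a median of 0.03, a mean of −0.10 and an upward camera direction (adjusted p = 0.73).

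Of 10 interstitial cell and subepithelial fibroblast markers, 5 fell and 2 rose, against 6 and 2 adjusted over the list alone. Kit, the receptor of interstitial cells of Cajal, fell from 180 ± 17.1 to 88.8 ± 10.9 CPM (−1.02 ± 0.09, adjusted p = 0.0001), the chloride channel gene Ano1 by 0.56 ± 0.10 and Etv1 by 0.72 ± 0.15, and Foxl1 and Gli1 were lower as above. Gja1 rose by 0.30 ± 0.04 and Thy1 by 1.02 ± 0.27, the latter without a call when wild type replicate 3 (adjusted p = 0.061) or YAP5SA replicate 1 (0.055) was left out, leaving 1 rise. The list missed the camera threshold (adjusted p = 0.064; adjusted p = 0.22 with an estimated correlation), and passed it only without wild type replicate 3 (0.027), without YAP5SA replicate 4 (0.046) or with sex as a covariate (0.05). Fry, which tests a list against no change and not against other genes, gave 0.0025.

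**Figure D2:**
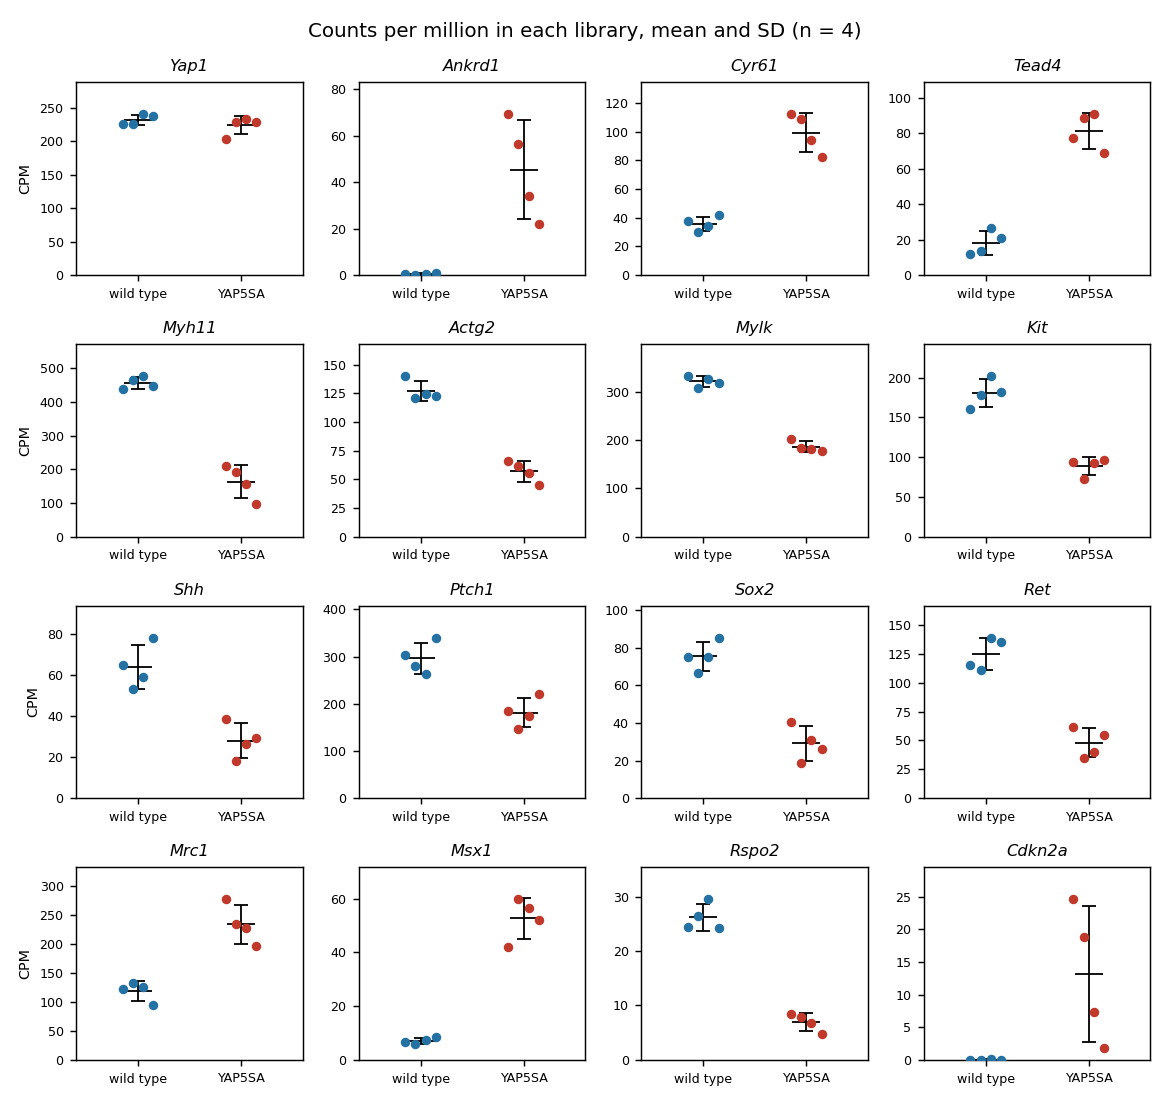
CPM of 16 genes in each library on linear axes from 0, wild type in blue and YAP5SA in red, with the mean and SD of 4 libraries per genotype in black. Myh11, Kit, Sox2 and Ret were lower in all 4 YAP5SA libraries, and Cdkn2a ranged from 1.88 to 24.6 CPM among them.

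Of 23 genes of BMP and TGF-beta signalling, 10 rose and 1 fell, against 13 and 1 adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.077 with an estimated correlation). Msx1, a homeobox gene induced by BMP, went from 6.99 ± 1.13 to 52.7 ± 7.75 CPM (2.91 ± 0.15, adjusted p = 4.8e-06). The BMP antagonist gene Nog rose by 1.98 ± 0.16, and the inhibitory Smad genes Smad7 and Smad6 by 0.78 ± 0.08 and 0.56 ± 0.06. Bmp5 fell by 1.04 ± 0.15. Bmp4 and Tgfb2 are on other lists too. Of 20 Wnt targets and modulators, 10 rose and 3 fell, against 11 and 3 adjusted over the list alone (camera adjusted p = 0.02; adjusted p = 0.35 with an estimated correlation). The Wnt inhibitor gene Wif1 rose by 3.61 ± 0.35, Wnt11 by 1.77 ± 0.13, the transcription factor genes Lef1 and Tcf7 by 1.71 ± 0.26 and 0.74 ± 0.06, and the feedback target Axin2 by 0.58 ± 0.07. Rspo2, an amplifier of Wnt signals, fell by 1.91 ± 0.17, from 26.2 ± 2.47 to 6.96 ± 1.58 CPM, and Dkk3 and Rnf43 fell by 0.66 ± 0.08 and 0.69 ± 0.14. Without YAP5SA replicate 1 the Wnt list lost its call (adjusted p = 0.084) and 5 members fell.

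Patterning genes of the stomach mesenchyme went both ways. Of 18 tested, 3 rose and 4 fell, and as many adjusted over the list alone (camera adjusted p = 0.81, direction down, median 0.00, mean 0.05). Gata3 rose by 1.44 ± 0.21 and Hand1 by 1.48 ± 0.45, while Pitx1 fell by 0.63 ± 0.08, Six2 by 0.84 ± 0.11, Foxf2 by 0.85 ± 0.15 and Nkx2-5 by 0.63 ± 0.18. Barx1, a mesenchymal regulator of stomach identity, was at 171 ± 7.64 and 158 ± 14.2 CPM (adjusted p = 0.28). Hand1 lost its call without any library but YAP5SA replicates 1 and 3 (adjusted p 0.062 to 0.1) and by limma-voom (0.1), and only 1 gene of the list rose without wild type replicate 1, 2 or 4 or YAP5SA replicate 2 or 4. Nkx2-5 lost it without wild type replicate 1 (0.066) or 2 (0.11) or YAP5SA replicate 2 (0.08) or 4 (0.066). Of its members, 5 are shared with other lists, among them Barx1, Nkx2-5 and Tcf21 with the spleen list and Foxf2 with the YAP list. Of 11 tested chondrogenic markers, 3 rose and 0 fell, against 4 and 0 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.15 with an estimated correlation). These were the cartilage matrix genes Matn3 (3.73 ± 0.44) and Col2a1 (1.03 ± 0.25) and the transcription factor gene Runx2 (1.63 ± 0.44). Col2a1 lost its call without YAP5SA replicate 3 (0.059) or 4 (0.05), and Runx2 without wild type replicate 1 (0.065) or 3 (0.067), under the replicate block (0.052) and by limma-voom (0.058). Without YAP5SA replicate 1 its log2 fold change was 1.03.

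The proliferation list had a median log2 fold change of 0.01 and a spread of 0.09 (SD over 31 tested genes, camera adjusted p = 0.5). It was densely covered, at a median of 0.31 fragments per exonic base, as were the matrix (0.336) and SRF/MRTF (0.385) lists. At such densities counts rose with depth by a log-log slope of 0.35 within genotypes, so changes in these 3 lists may be compressed. The smooth muscle (0.231), patterning (0.251) and spleen (0.272) lists lay at densities with a slope of 0.50, so their changes may be compressed too. Bub1, a spindle checkpoint gene, rose by 0.19 ± 0.06 (adjusted p = 0.04), and 0 genes fell; adjusted over the list alone, 0 rose and 0 fell. Bub1 lost its call without any library but wild type replicate 4 (adjusted p 0.052 to 0.095), and 3 members rose without YAP5SA replicate 1. Under the replicate block, and without wild type replicate 2, the cyclin gene Ccne2 (0.23 ± 0.08, adjusted p = 0.056) passed, at 0.028 and 0.033. Of 25 extracellular matrix genes, 2 rose and 5 fell, and as many adjusted over the list alone (camera adjusted p = 0.52, direction down, median −0.05, mean 0.00). Fbln5 rose by 0.53 ± 0.08 and Bgn by 0.33 ± 0.09, and the collagen genes Col6a3, Col6a1, Col6a2 and Col3a1 fell by 0.65 ± 0.11, 0.32 ± 0.06, 0.27 ± 0.07 and 0.22 ± 0.05 and Lum by 0.30 ± 0.08. Bgn lost its call without wild type replicate 2 or 4 or YAP5SA replicate 1, 2 or 3 (0.05 to 0.085), Lum without wild type replicate 1 or 2 or YAP5SA replicate 2, 3 or 4 (0.064 to 0.08), and Col6a2 without any library but wild type replicate 4 and YAP5SA replicate 1 (0.053 to 0.081). Matrix genes numbered 4 rises without wild type replicate 3 and 1 rise without wild type replicate 2 or 4 or YAP5SA replicate 2 or 3, and 3 falls without wild type replicate 1 or 2 or YAP5SA replicate 2, 3 or 4. Of 14 tested SRF/MRTF and actin cytoskeleton targets, Zyx (0.19 ± 0.05) and Filip1l (0.18 ± 0.05) rose and Fhl2 (−0.49 ± 0.12) and Actb (−0.15 ± 0.05) fell, 2 and 2 also adjusted over the list alone (camera adjusted p = 0.44). Zyx lost its call without wild type replicate 2 (0.054) or 4 (0.063) or YAP5SA replicate 3 (0.055), which left 0 rises in those fits, and Fhl2 without wild type replicate 1 (0.054) or YAP5SA replicate 4 (0.057), which left 0 falls. Filip1l lost it without wild type replicate 2 or 4 or YAP5SA replicate 2 or 3 (0.055 to 0.083) and under the block (0.052), and Actb without any library but wild type replicate 2 (0.076 to 0.095) and under the block (0.062).

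Markers of the epithelium and of the enteric nervous system fell together. Of 22 tested epithelial markers, 21 fell and 0 rose, and as many adjusted over the list alone (camera adjusted p = 1.1e-12; adjusted p = 0.22 with an estimated correlation). Sox2, a foregut regulator, fell by 1.36 ± 0.19, from 75.4 ± 7.70 to 29.1 ± 9.23 CPM, Cldn7 by 0.96 ± 0.12, Cldn6 by 0.71 ± 0.06, Cdh1 by 0.72 ± 0.15 and Epcam by 0.69 ± 0.09. Basal cell genes of the squamous forestomach fell, Krt5 by 1.87 ± 0.41, Krt15 by 1.40 ± 0.31 and Trp63 by 1.73 ± 0.31, as did genes of the glandular stomach, Cldn18 by 1.90 ± 0.42, Hnf4a by 1.18 ± 0.16 and Gata4 by 0.64 ± 0.12. Without YAP5SA replicate 3, Krt5 (adjusted p = 0.05), Krt15 (0.054) and Cldn18 (0.058) lost their calls, and without YAP5SA replicate 1 Cldn18 was at −2.62. Ehf stood at 24.0 ± 17.4 and 14.9 ± 11.4 CPM (adjusted p = 0.43; 0.0026 under the replicate block), a log2 fold change of −0.68 that was −0.03 without wild type replicate 1 and −1.37 without YAP5SA replicate 1. Of 15 enteric neuron genes, 11 fell and 0 rose, against 13 and 0 adjusted over the list alone (camera adjusted p = 1.5e-10; adjusted p = 0.08 with an estimated correlation). The receptor gene Ret fell by 1.38 ± 0.16, from 125 ± 14 to 48.0 ± 12.6 CPM, Tubb3 by 1.05 ± 0.07 (adjusted p = 2.1e-05), Stmn2 by 0.83 ± 0.06 and Stmn3 by 1.38 ± 0.16. Of 7 tested glial and neural crest genes, 6 fell and 0 rose, and as many adjusted over the list alone (camera adjusted p = 4.9e-06; adjusted p = 0.077 with an estimated correlation). They included Sox10 (−1.39 ± 0.12), Foxd3 (−1.68 ± 0.20), Erbb3 (−1.04 ± 0.19), Fabp7 (−0.79 ± 0.12) and Ednrb (−0.61 ± 0.08).

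Most macrophage markers rose, and 1 endothelial marker did. Of 12 tested macrophage and leukocyte genes, 10 rose and 0 fell, against 11 and 0 adjusted over the list alone (camera adjusted p = 1.3e-06; adjusted p = 0.35 with an estimated correlation). The mannose receptor gene Mrc1 went from 119 ± 16.6 to 234 ± 33.2 CPM (0.98 ± 0.12, adjusted p = 0.00042), Cx3cr1 rose by 0.94 ± 0.10, Emr1 by 1.09 ± 0.20, C1qb by 0.65 ± 0.12 and Csf1r by 0.61 ± 0.11. Of 15 endothelial genes, Kdr, a VEGF receptor gene, rose by 0.62 ± 0.07 and 0 fell, and as many adjusted over the list alone (camera adjusted p = 0.58, direction up, median −0.02, mean 0.04). Without wild type replicate 2, Flt1 (0.37 ± 0.14, adjusted p = 0.11) also passed (0.019), for 2 rises. Of 10 mesothelial genes, 4 fell and 0 rose, against 6 and 0 adjusted over the list alone (camera adjusted p = 0.0047; adjusted p = 0.35 with an estimated correlation). Besides Cldn15, Krt19 fell by 0.57 ± 0.09, Upk3b by 0.47 ± 0.13 and Rspo1 by 0.51 ± 0.15, while Wt1, shared with the spleen list, was at 112 ± 24.7 and 130 ± 8.80 CPM (adjusted p = 0.32). Upk3b lost its call without wild type replicate 2 or 3 or YAP5SA replicate 2, 3 or 4 (0.052 to 0.085), and Rspo1 without wild type replicate 2 or 3 or YAP5SA replicate 1, 2 or 3 (0.08 to 0.097), so 2 fell without wild type replicate 2 or 3 or YAP5SA replicate 2 or 3. Of 6 genes of the spleen primordium, 5 of them shared with other lists, Nkx2-5 fell, except in the fits that lost its call as above, and 0 rose, and as many adjusted over the list alone (camera adjusted p = 0.77). Of 8 tested erythroid genes, 2 fell, among them Hbb-y by 0.26 ± 0.06, and 0 rose, as many adjusted over the list alone (camera adjusted p = 0.066; adjusted p = 0.35 with an estimated correlation). That list passed camera under the replicate block (0.035) and without YAP5SA replicate 4 (0.018) but in no other camera fit, and fry, against no change, gave 0.027. Only 1 member fell without wild type replicate 1, 2 or 3 or YAP5SA replicate 2 or 3. Hbb-y shares sequence with other globin genes, so its count is uncertain.

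Transcripts of liver and skeletal muscle were higher in YAP5SA. Of 9 tested liver genes, 7 rose and 0 fell, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.52 with an estimated correlation). The albumin gene Alb went from 10.2 ± 5.53 to 63.5 ± 35.1 CPM (2.63 ± 0.54), Afp from 21.6 ± 9.60 to 83.7 ± 37.7 CPM (1.95 ± 0.43), Apob rose by 2.78 ± 0.53, Trf by 0.91 ± 0.17, Ahsg by 3.13 ± 0.73, Apoa2 by 2.38 ± 0.69 and Fgb by 2.30 ± 0.70. Fgb was at 2.86, 0.588, 0.6 and 0.158 CPM in wild type and rose by 3.48 without wild type replicate 1, and Ahsg rose by 3.77 without wild type replicate 3. The rise lay mainly in YAP5SA replicates 2, 3 and 4, since replicate 1 was the lowest of its group in all 7 genes and within the wild type range in Apoa2 and Fgb. It was at 18.8 CPM of Alb, beside 52.3 to 93.8 in the others and up to 15.3 in wild type, and at 31.1 CPM of Afp, beside 81.6 to 112 and up to 28.9. By limma-voom 2 liver genes rose, as Alb (0.13), Afp (0.091), Apob (0.08), Apoa2 (0.18) and Fgb (0.058) lost their calls. Apoa1 was at 25.5 ± 4.05 and 17.1 ± 5.70 CPM (adjusted p = 0.1) and Ttr at 36.4 ± 13.8 and 28.2 ± 3.02 CPM (adjusted p = 0.29). The liver list lost its call without YAP5SA replicate 2 (0.05), with the stricter filter (0.31) and by fry (0.079). Under the replicate block Alb (0.11), Afp (0.15) and Fgb (0.14) lost theirs, as did Apoa2 without any library but YAP5SA replicate 1 (0.059 to 0.092) and Fgb without any but wild type replicate 1 and YAP5SA replicate 1 (0.085 to 0.12). Of 9 tested skeletal muscle genes, 5 rose and 0 fell, and as many adjusted over the list alone (camera adjusted p = 0.00097; adjusted p = 0.35 with an estimated correlation; 0.082 with the stricter filter). These were the myogenic regulators Myod1 (3.53 ± 0.73) and Myog (2.74 ± 0.59) and the sarcomere genes Actn2 (1.83 ± 0.42), Tnni1 (0.98 ± 0.30) and Tnnt1 (0.41 ± 0.08). Here too YAP5SA replicate 1 was the lowest of its group in 4 of the 5, at 2.28 CPM of Myod1, beside 8.15 to 17.7 in the others and up to 2.22 in wild type. Without wild type replicate 1, Myod1 rose by 4.70 and Myog by 3.39. Tnni1 lost its call without wild type replicate 2, 3 or 4 or YAP5SA replicate 3 or 4 (0.084 to 0.11), under the block (0.072) and by limma-voom (0.083). In the pancreas list 0 of 10 tested genes passed edgeR's, DESeq2's or limma-voom's threshold, and 0 at an unadjusted p under 0.05 by edgeR or adjusted over the list alone (camera adjusted p = 0.87, direction up, median −0.27, mean −0.24). Of 3 tested intestinal genes, Vil1 fell by 1.42 ± 0.43 and 0 rose, as many adjusted over the list alone (camera adjusted p = 0.2; 0.012 under the replicate block, where Cdx2 also passed at 0.029). Vil1 lost its call without any library but wild type replicate 3 and YAP5SA replicate 1 (0.078 to 0.11).

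**Figure D3:**
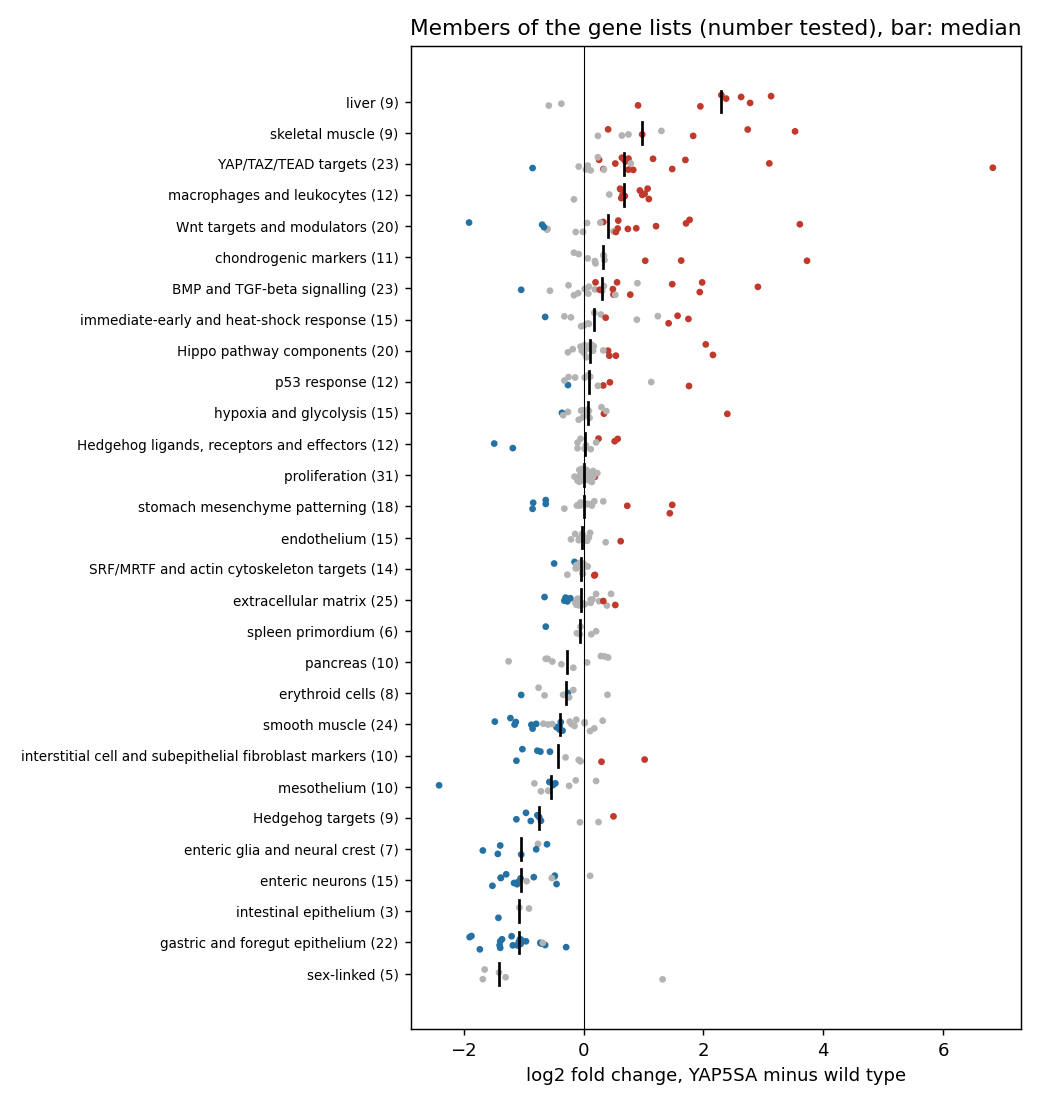
Log2 fold changes, YAP5SA minus wild type, of the tested members of the 29 gene lists (x axis), with 1 line of points per list, the number tested in brackets and a black bar at the median (n = 4 per genotype). Red points rose and blue points fell at the adjusted p threshold and grey points did not pass, and medians run from −1.07 for the epithelium, with −1.41 for the sex-linked genes, to 2.30 for the liver.

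Stress and handling genes showed single changes without a shift of a whole list. Of 15 tested immediate-early and heat-shock genes, 4 rose and 1 fell, against 6 and 2 adjusted over the list alone (camera adjusted p = 0.17). Ier3 rose by 1.57 ± 0.29, Dusp1 by 0.37 ± 0.10 and the near-identical copies Hspa1a and Hspa1b, whose split of fragments is uncertain, by 1.75 ± 0.48 and 1.42 ± 0.39, and Btg2 fell by 0.64 ± 0.12. YAP5SA replicate 2 was at 27.8 CPM of Hspa1a beside 9.34, 6.07 and 7.65, and without it Hspa1a rose by 1.05 and Hspa1b by 0.84. Dusp1 lost its call without wild type replicate 4 (adjusted p = 0.062) or YAP5SA replicate 3 (0.056), Hspa1a without wild type replicate 1 (0.062), 2 (0.076) or 4 (0.075), and Hspa1b without the same libraries (0.071, 0.081 and 0.068) and under the block (0.062), and both by limma-voom (0.077 and 0.089), so 2 rose without wild type replicate 2 and 1 without wild type replicate 4. Of 15 hypoxia and glycolysis genes, Adm rose by 2.40 ± 0.31 and the glucose transporter gene Slc2a1 by 0.34 ± 0.07, and Egln3 fell by 0.36 ± 0.10, 3 and 1 adjusted over the list alone (camera adjusted p = 0.5). Egln3 lost its call without any library but YAP5SA replicate 1 (0.062 to 0.11), where 2 fell. Of 12 p53 response genes, Aen (0.44 ± 0.10), Eda2r (1.76 ± 0.44) and Ccng1 (0.33 ± 0.09) rose and Trp53inp1 fell by 0.26 ± 0.08, 4 and 1 adjusted over the list alone (camera adjusted p = 0.29). Eda2r lost its call without wild type replicate 2 (0.058), where 1 rose, Ccng1 without wild type replicate 2, 3 or 4 or YAP5SA replicate 1 or 2 (0.052 to 0.077), and Trp53inp1 without any library but wild type replicate 3 and YAP5SA replicate 4 (0.065 to 0.13). By Xist and Y-linked genes, wild type replicates 1, 2 and 3 and YAP5SA replicate 2 were male and the other 4 libraries female. Of the 5 sex-linked genes 0 passed edgeR's, DESeq2's or limma-voom's threshold, and 0 at an unadjusted p under 0.05 by edgeR or adjusted over the list alone (camera adjusted p = 0.44). Without YAP5SA replicate 2, the only male library of its group, Kdm5d passed (0.038).

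Fits other than those without 1 library also ended calls of named genes. With embryo sex as a covariate 2219 loci passed, 1997 of the 2757 kept their calls, and 19 of 160 named genes lost theirs. Among these were Tead1 (adjusted p = 0.092), Runx2 (0.11), Col2a1 (0.09), Nkx2-5 (0.13), Hand1 (0.096), Lum (0.1), Col6a2 (0.12), Bub1 (0.14), Actb (0.093), Fhl2 (0.052), Upk3b (0.14), Rspo1 (0.068), Tnni1 (0.16), Vil1 (0.082), Dusp1 (0.054), Egln3 (0.096) and Trp53inp1 (0.056), while Myocd (0.034) and Ccne2 (0.037) passed. The FPKM fits ended 18, 16 and 21 named calls, in all 3 of them those of Col2a1, Runx2, Upk3b, Nkx2-5, Hand1, Gli1, Krt15, Afp, Apoa2, Egln3 and Trp53inp1 (0.053 to 0.17). Without a filter on low counts 11 calls ended, among them Actb (0.07), Col2a1 (0.053), Nkx2-5 (0.052), Vil1 (0.069), Trp53inp1 (0.055), Gli1 (0.073), Cldn18 (0.05) and Fgb (0.062).

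No locus held more than 8330 fragments in any library, and the 10 most abundant loci held 0.63% to 0.71%. Within genotypes, loci with at least 0.5 fragments per exonic base rose with depth by a log-log slope of 0.22 ± 0.05. With the greater depth of the YAP5SA libraries that slope gives a log2 fold change of −0.18 without any change in expression, and the median over these loci was −0.09. Among them were Col3a1, Actb and Hbb-y, at 0.739, 0.759 and 0.814 fragments per base, with 16455, 5697 and 2088 fragments in wild type and 16457, 5968 and 2035 in YAP5SA, so their falls of 0.22, 0.15 and 0.26 are not told apart from this saturation. Few of these densely covered loci had a fitted change of at least 2-fold, 0.9% against 21% among the 3861 sparsest loci. The shares called were 11.8% and 26.2%. The sparsest loci held 4.7% of the fragments, and counting error widens their fitted changes, so these shares do not measure saturation.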

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

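The tests weighed here, on dilution, embryo sex, stomach region, fragment ceilings, duplicate removal and adhering tissue, were all chosen after the results were seen. A library was singled out where it lay far from the other 3 of its group. This held for 44 of 384 groups of 4 values, where chance flags about 1 in 20 groups, or 19.2 here.

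Markers of epithelium, enteric neurons and enteric glia were lower in YAP5SA, with a median of −1.09 over the 38 called members. A larger mesenchyme diluting all other cells alike is argued against by the endothelial median of −0.02 (SD 0.21) and the macrophage median of 0.67. These medians cannot decide on a mesenchyme that grew together with its vessels and macrophages and diluted only epithelium and nerves. Unequal embryo sex is argued against by a median of −1.26 (median SE 0.18) with sex as a covariate, where 37 of the 38 kept their calls. A shift between squamous and glandular stomach in the dissected tissue is argued against because both fell, squamous markers by a median of −1.73 and glandular markers by −1.18 (3 genes each). Fewer epithelial and neural cells, a smaller share of them, or lower expression in each are explanations that whole-tissue values leave untested.

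Abundant loci held few fragments, with no value above 8330. A few genes taking most fragments is argued against by the 10 most abundant loci, which held at most 0.71%. A fixed ceiling is argued against because only 1 locus lay within 5 percent of the highest count in any library. Removal of fragments at the same position may account for it, since the slope on depth within genotypes went from 1.21 for the sparsest loci through 0.91, 0.68, 0.50 and 0.35 to 0.22 ± 0.05 for the densest. Setting each gene against the median of loci of like density left list medians nearly as they were, −0.40 and −0.38 for smooth muscle. Those density medians lay between −0.09 and 0.02, so this step could hardly move a list. It cannot show whether saturation shrank the fold changes of dense loci. Small falls of the densest loci, as of Col3a1, Actb and Hbb-y, may come from saturation, which gives −0.18 at the slope of 0.22.

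Liver and skeletal muscle transcripts were higher in YAP5SA, mainly in replicates 2, 3 and 4, with replicate 1 the lowest of its group in all 7 called liver genes and in 4 of 5 called muscle genes. Adhering liver cannot be told apart from expression in the stomach, since 7 of 9 tested liver markers rose while the abundant Apoa1 and Ttr, at 17.1 and 28.2 CPM beside 63.5 CPM of Alb and 83.7 CPM of Afp, did not. Adhering skeletal muscle stays open likewise, with 3 of 7 tested sarcomere markers past the threshold and a median of 0.75. Both would enter at dissection, and a direct effect of YAP5SA on these genes was not tested.

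Other values far from their group are given in CPM, with no explanation tested. In wild type replicate 1, 9 genes stood apart, with Cdkn2b at 4.13, Pgc at 16.8, Actg2 at 140, Apob at 1.43, Myod1 at 2.22, Cldn18 at 114, Ehf at 49.9, Fgb at 2.86 and Alx1 listed at 0. In YAP5SA replicate 1, 11 genes stood apart, with Yap1 at 204, Cacna1s at 39.3, Mcm6 at 189, Actb at 186, Runx2 at 23.4, Hapln1 at 23.8, Cldn7 at 38.2, Etv1 at 30.4, Ehf at 31.9, Hoxb9 at 16.9 and Hoxd3 at 28.0. Wild type replicate 2 was low in Hoxd3 at 36.0, and wild type replicate 3 was high in Wwtr1 at 165, Cdkn2a at 0.15 and Rxfp1 at 0.6. Wild type replicate 4, the female library of its group, had Xist at 1070, Ddx3y at 0.158 and Uty and Kdm5d at 0, and stood apart in Ednrb at 161, Hbb-y at 84.3 and Hoxa9 at 4.42. YAP5SA replicate 2, the male library of its group, had Xist at 0.967, Uty at 39.7, Eif2s3y at 83.5, Kdm5d at 118 and Ddx3y at 124, and stood apart in Kit at 72.5, Hspa1a at 27.8 and Hspa1b at 42.6. YAP5SA replicate 3 was high in Alx1 at 20.9. It was also flagged in Bub1 at 141, but only because the others were all at 139 after rounding, so it hardly stood apart there. YAP5SA replicate 4 was low in Kdr at 190 and high in Slc4a1 at 40.2 and Trp53inp1 at 55.7.

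Loci without a gene name stayed outside the comparison, and 102 of 2355 tested passed the threshold by edgeR, 48 higher and 54 lower in YAP5SA. At XLOC_022572 (chromosome 7, 88530395 to 88530550, mm10) the wild type libraries had 53, 70, 66 and 68 fragments and the YAP5SA libraries 0, 0, 0 and 1, a CPM ratio of 300.0 (95% counting interval 53.4 to 11900) of wild type over YAP5SA, or at least 75.4 against 3 fragments without YAP5SA replicate 4. This locus was chosen after its values were seen.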

How the results depend on the processing

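Embryo sex as a covariate, leaving out both libraries numbered 1 and the restriction to sparsely covered loci were chosen after seeing the data. The count of changed loci, 2757, ran from 2032 without YAP5SA replicate 3 to 2805 without YAP5SA replicate 1 and to 3035 with the replicate block. Loci changed at least 2-fold, 919, ran from 733 to 1057 when single libraries were left out and numbered 983 with the block. They fell to 519 on log2(FPKM + 1) and 522 without its filter, where the pseudocount shrinks the folds of low genes, and 3 calls changed sign in each FPKM fit. Of the 29 lists, 0 passed camera with an estimated correlation, with adjusted p of 0.15 for smooth muscle, 0.077 for YAP targets and 0.35 for Hedgehog targets. The Hedgehog targets ran from 0.0063 to 0.079 when single libraries were left out, the highest without YAP5SA replicate 1, and were at 0.11 without both libraries numbered 1. Of 192 named genes, 160 were called, 123 of them whichever library was left out and 119 in every alternative. The block ended 9 of those calls and added 3, and 2568 of the 2757 loci kept theirs. With sex as a covariate 2219 loci passed, 1997 of the 2757 kept their calls, and 19 named calls ended and 2 were added. Limma-voom ended 13 and added 1, the fit without a filter on low counts ended 11, and the FPKM fits ended 18, 16 and 21.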

Other observations

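All tests in this part were chosen after the results were seen, except the count of passing lists over the splits. Of 13 tested Wnt ligand genes, which were grouped after their values were seen, 7 rose and 0 fell by edgeR, and as many with RLE or upper-quartile factors. Besides Wnt7a and Wnt11, Wnt6 went from 2.27 ± 0.481 to 32.4 ± 8.09 CPM (3.83 ± 0.24, adjusted p = 1.1e-05), Wnt3 rose by 1.83 ± 0.37, Wnt7b by 1.32 ± 0.31, and Wnt4 and Wnt5a also rose. Among type IV collagen genes, Col4a3 and Col4a4 rose, the latter from 3.39 ± 1.24 to 47.9 ± 12.4 CPM (3.81 ± 0.27), and the other 4 tested did not pass, except that Col4a1 fell with upper-quartile factors. Col4a3 and Col4a4 are neighbours that share a promoter region.

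Hox genes went both ways, with 6 of 18 tested higher and 2 lower, and 7 and 2 with RLE factors. Hoxb9, which belongs to the posterior end of its cluster, rose by 1.84 ± 0.28, Hoxa9 by 1.68 ± 0.30 and Hoxd8 by 1.35 ± 0.29. Hoxd3 fell by 1.02 ± 0.14 and Hoxa4 by 0.38 ± 0.10, the latter losing its call without any library but wild type replicate 1 and YAP5SA replicate 4 (adjusted p 0.061 to 0.077). A joined locus of Hoxa3 and Hoxa4 on the same coordinates, counted apart, was at −0.02 (adjusted p = 0.96). The cell cycle inhibitor genes Cdkn2a and Cdkn2b, at 0.044 and 0.08 fragments per exonic base, rose while the proliferation list had a median of 0.01. That list had a median density of 0.31 fragments per base, where counts rose with depth by a slope of 0.35. A change in it may therefore be compressed, and its median does not show that proliferation stayed the same.

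For the number of changed loci, 2757, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many. The highest other split, which parted the male from the female libraries, gave 6. For the 919 loci changed at least 2-fold, 1 of 35 splits gave as many, and the highest other gave 5. Every other split mixes the genotypes, so a genotype difference widens the spread within its sides and lowers its count. These counts therefore give no chance level, and chance is not excluded by them. For the number of passing lists, 5 of 35 splits gave as many as the real 14 and the highest other gave 16. Besides the real one, these splits kept 3 of the 4 libraries of a genotype on 1 side. They carry part of the genotype difference and give no chance level either. Splits with 2 libraries of each genotype on a side gave up to 9 lists. Chance is not excluded for this count, and the splits cannot decide it. The mean of 13 of the 29 lists was largest in the real split, each at the smallest exact p of 0.0286, and 0 lists passed after adjustment (lowest adjusted p = 0.064). With 35 splits no exact p can be smaller, so a list could pass the adjustment only if more than 13 lists reached that floor. The adjusted values therefore decide nothing about single lists. The 7 other splits that part all 4 same-numbered pairs gave 0 loci and up to 14 lists. With the libraries taken as pairs, only 8 splits apply, too few for a share under 0.05.

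A candidate explanation for the lower Hedgehog ligands is that Shh and Ihh fell with the epithelium that makes them. The genotypes differed by −0.23 in the mean log2 CPM of Shh and Ihh minus that of 22 epithelial markers (SD 0.25 in wild type and 0.33 in YAP5SA, n = 4; exact two-sided permutation p = 0.314), and a further fall of the ligands is not excluded. That Hedgehog targets follow the ligands within genotypes stays open. Over the 8 libraries' deviations from their genotype means, targets and ligands gave a Pearson r of 0.48 (permutation p = 0.2) and a Spearman rho of 0.55 (permutation p = 0.18), from 576 permutations within genotypes, and r was 0.75 without the 2 libraries farthest from the ligand median.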
